A study of Mus musculus with 9 samples.

How the data were processed

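The data are RNA-seq libraries of mouse intraperitoneal macrophages: 3 with LPS, 3 with DHA before LPS and 3 with cpdA before LPS, grouped by their titles. The deposited table holds 1 signal value per gene and library, which the authors made by dividing read counts by 1 size factor per library, as the values show and as the normalization tool DESeq, per the submitters' processing notes, would give. Those notes also name CASAVA 1.8.2 for base calling, Bowtie2 for alignment and the genome build mm9. The counting program, the annotation, the library kit and the use of strand are not given in the sources used here, so antisense and overlapping genes cannot be told apart. The growth and extraction protocols in the labels describe neural stem cells and histone-bound DNA, which belong to other kinds of experiment and were not used, and the strain is written CF7B1/6. The table names genes by Entrez number and symbol. No coordinates are given, because the reference at hand is of another build.

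Between 99.8% and 99.99% of the values in each library were multiples of 1 step, the worth of 1 read, within a rounding of 0.05, and all values were rounded to whole reads. Recovered depth ranged from 13797079 to 37572822 reads. A count of 0 was taken to allow up to 3 reads, which covers counting error only. Reads shared between near-identical copies (Serpina3h, Gm and LOC genes, the pseudogene Art2a-ps) make the values of those genes uncertain.

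Genes were kept with a normalized count of at least 10 in at least 3 of the 9 libraries, which left 13895 of 15343. The values as deposited were analysed as log2(value + 1) in limma 3.58.1 (R 4.3.3, with statmod 1.5.0) with a mean for each group, all 9 libraries in 1 fit, and empirical Bayes moderation with trend and robust options. Changes are on that log2 scale, which understates those of genes with low counts. Adjusted p-values are Benjamini-Hochberg over the genes kept, with a threshold of 0.05. The 33 gene lists were fixed before the data were examined, as were the filter, the tests and the rule for named genes. 716 of their 779 entries were found in the table, 8 of them by an older symbol. Lists with at least 5 kept members, 32 in all, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 96 tests. The same tests were run with an estimated correlation and with fry. List members were also adjusted over the list alone. The erythrocyte and platelet list had 2 kept members and was not tested.

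The rule for named genes took, for each comparison with LPS, the 10 largest rises and the 10 largest falls among called genes that had a mean of at least 50 in the higher group and all treated libraries on one side of all LPS libraries. It also took members of the lists described and a fixed set of inflammatory and lipid genes with Ffar4. Since all-library fits called few genes, the rule was also applied to a fit without cpdA 3 and LPS 3. That fit, a batch term for these libraries, library weights, a fit without DHA 1 and cpdA 1, fits without cpdA 3, LPS 3 and either DHA 1 or cpdA 1, blocked fits of the LPS and cpdA libraries and of 7 libraries, and the count tests on 7 libraries were alternatives chosen after seeing the data. Examples of list members are named only for the 6 lists with the smallest camera p in each comparison with LPS, a limit also set after seeing the data and without regard to how stable a gene was. The clock gene list was likewise made after seeing the data.

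Alternatives fixed in advance were pseudocounts of 0.5 and 8, other filters, TMM, median-of-ratios and quantile scaling, limma without trend and robust options, a replicate block, only the libraries compared, stricter thresholds and each library left out in turn. The counts of recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0, on the same kept genes and, for DESeq2, with independent filtering at 0.05. DESeq2 gave no adjusted p for 279, 1895 and 9 genes in the DHA, cpdA and cpdA against DHA comparisons. The correlation of changes between compounds was set beside 100 draws of unchanged groups against the same simulated LPS libraries. The overlap of calls was too, with the draws fitted in limma. The draws took genes as independent and let the groups share only the LPS libraries, so other variation common to real libraries is left out. The labels do not say what a replicate number marks. Deviations from the group means of same-number libraries correlated across genes at 0.234 to 0.437 in all 3 pairs of LPS and cpdA, so by the rule of over 0.1 in each pair these are taken as paired for that comparison and the blocked value stands beside its result. 2 of the 6 pairs with other numbers also exceeded 0.1: LPS 2 with cpdA 1 (0.292) and LPS 1 with cpdA 2 (0.264). Both lay above LPS 2 with cpdA 2 (0.234). Deviations cancel out within a group, so with LPS 3 and cpdA 3 both apart the 3 pairs are not separate evidence. The pairing is at most a hint from the data, not from the design. For DHA against LPS and cpdA against DHA, 1 of 3 pairs exceeded 0.1, and no pairing is taken. Each comparison was also computed for all 10 splits of its 6 libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

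The scripts were tested on simulated counts with 100 genes changed by 2-fold and 100 by 4-fold among 13895. With 9 libraries, 77% of 2-fold and 95% of 4-fold changes were recovered for DHA against LPS, 68% and 99% for cpdA against LPS, and 67% and 97% for cpdA against DHA, with 5 to 9 false calls. With 7 libraries, recovery was 88% and 100%, 95% and 99%, and 94% and 100%, with 8 to 14 false calls. The simulated counts gave each gene the same spread in every library, and no library stood apart. These shares are thus no guide to how many changes the fits of the real libraries find. A raised list was called in all 6 simulated comparisons and 0 of 31 other lists were, with simulated genes independent of each other. Nothing in the labels says whether replicates are separate animals or cultures, so p-values measure only the spread between these libraries.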

Results

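RNA was sequenced from mouse intraperitoneal macrophages, all marked WT (wild type) in their titles. All were stimulated with lipopolysaccharide (LPS), the bacterial cell wall component sensed by the receptor TLR4, at 100 ng/ml for 6 h. Before LPS, one group received 100 µM DHA (docosahexaenoic acid, an omega-3 fatty acid) for 1 h. A second group received 10 µM cpdA for 1 h, which the labels call an agonist of Gpr120, the fatty acid receptor encoded by Ffar4. The control group received LPS with no pretreatment given in its labels, and each group had 3 libraries. Each comparison with LPS therefore covers the pretreatment step as well as the compound. No unstimulated libraries were analysed here, so each comparison concerns the LPS-stimulated state. The reads recovered from the normalized counts numbered 29128175, 27169850 and 29521323 in LPS 1, 2 and 3, 13797079, 24842170 and 26671807 in DHA 1, 2 and 3, and 29048332, 37572822 and 27144068 in cpdA 1, 2 and 3. Of 15343 genes in the table, 13895 were kept for testing.

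The libraries of a group were not equally alike. The first principal component held 40.5% of the variance and set cpdA 3 apart, and the second held 28.8% and set LPS 3 apart. In cpdA 3, Il6, an inflammatory cytokine induced by LPS, had a normalized count of 126, and Il1b, another such cytokine, had 6840. In LPS 3, Il6 had 5043 and Il1b 83957. Against the mean of LPS 1 and LPS 2, the median of the proinflammatory cytokine list was -0.84 in LPS 3 and -2.72 in cpdA 3 (log2). The median of the cholesterol synthesis list was -1.02 in LPS 3 and -1.62 in cpdA 3, and that of the neutrophil marker list -0.96 and -1.33. A list of nuclear and mitochondrial transcripts, kept as a sign of RNA quality, had a median of 0.14 in LPS 3 and 0.79 in cpdA 3. The spread between cpdA 3 and cpdA 2 was 12.3 times sampling noise at equal depth, against 1.60 between LPS 1 and LPS 2 and 1.26 between DHA 1 and cpdA 1, which belong to different groups.

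**Figure D1:**
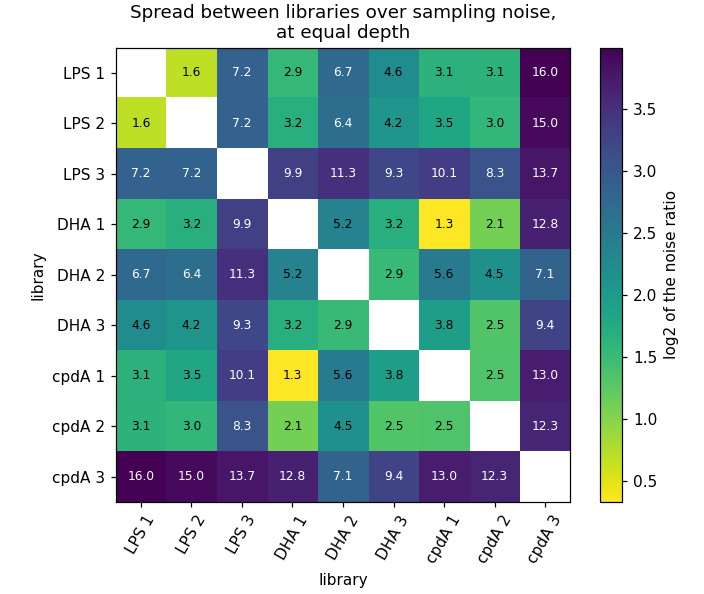
Spread between each pair of the 9 libraries, as a multiple of sampling noise with reads thinned to equal depth; the colour gives the log2 of that ratio and the printed number the ratio itself. The smallest value, 1.26, lies between DHA 1 and cpdA 1, and cpdA 3 lies 7.13 or more from every other library.

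The comparison of DHA + LPS with LPS asks what DHA pretreatment altered in stimulated macrophages. Cpt1a (Entrez 12894), which lets long-chain fatty acids into mitochondria for oxidation, rose. Its normalized count was 1628 ± 191 in LPS and 3436 ± 267 in DHA + LPS (SD, n = 3), a log2 change of 1.08 (SE 0.11; limma, Benjamini-Hochberg adjusted p = 0.0358), with all 3 DHA libraries above all 3 LPS libraries. As lists, targets of PPAR, ER chaperones and targets of NRF2 rose and interferon-stimulated genes fell, each against the other genes with camera's preset correlation. With an estimated correlation none of these calls held (smallest adjusted p = 0.096, limma). Cpt1a was the 1 gene of 13895 past the limma test, with 1967 genes at an unadjusted p under 0.05. The edgeR test on recovered reads called 3 genes and DESeq2 called 315. Left out singly, 7 libraries ended the Cpt1a call: its limma adjusted p was 0.270 without LPS 1, 0.297 without LPS 2, 0.145 without DHA 1, 0.140 without DHA 2, 0.398 without DHA 3, 0.137 without cpdA 1 and 0.0901 without cpdA 2. Without cpdA 3, limma called 373 genes, 154 higher and 219 lower, and without LPS 3 it called 2. The spread behind these tests was estimated over all 9 libraries. Leaving out cpdA 3, which is not compared here, leaves the DHA changes as they were and alters only that spread.

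Of 31 kept PPAR targets and fatty acid oxidation genes, 28 had a positive change with DHA, with a median of 0.35. 1 passed over all genes and 13 were higher when adjusted over the list alone (camera adjusted p = 3.8e-10). That call was lost with an estimated correlation (adjusted p = 0.096), and fry, which asks whether a list moves one way, gave an adjusted p of 0.00738. Beside Cpt1a, Hilpda, which coats lipid droplets and slows their breakdown, changed by 0.90 (SE 0.15; limma adjusted p = 0.159). Acads and Hadh, enzymes of mitochondrial beta-oxidation, changed by 0.42 and 0.84 (limma adjusted p = 0.183 for each). The list's median in LPS 3 was -0.11 against LPS 1 and LPS 2.

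All 22 kept ER chaperone and unfolded protein response genes had a positive change with DHA, with a median of 0.51. None passed over all genes and 14 were higher when adjusted over the list alone (camera adjusted p = 1.7e-12; adjusted p = 0.470 with an estimated correlation). Hspa5, the main chaperone of the ER, had 30451 ± 2214 normalized counts in LPS and 45841 ± 7056 in DHA + LPS (SD, n = 3), a log2 change of 0.58 with a limma adjusted p of 0.236. Herpud1, which takes part in ER-associated degradation, changed by 1.46 (SE 0.27; limma adjusted p = 0.183). Of 32 NRF2 targets, the antioxidant defence genes, 31 had a positive change with a median of 0.40, and 0 were higher either over all genes or adjusted over the list alone (camera adjusted p = 1.9e-07; adjusted p = 0.628 with an estimated correlation). Slc7a11, the cystine importer that feeds glutathione synthesis, changed by 1.52 (SE 0.64; limma adjusted p = 0.339), and Hmox1, the heme-degrading enzyme, by 0.77 (limma adjusted p = 0.294); with LPS 3 left out these values were 0.67 and 0.44. The NRF2 list had a median of -0.64 in LPS 3. Of 29 genes of the integrated stress response, the programme that follows phosphorylation of eIF2alpha, 23 had a positive change with a median of 0.27 (camera adjusted p = 0.00058; adjusted p = 0.642 with an estimated correlation). None of the 29 passed over all genes or adjusted over the list alone.

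All 40 interferon-stimulated genes, the antiviral genes induced by type I interferon, had a negative change with DHA, with a median of -0.65. 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 6.3e-12; adjusted p = 0.647 with an estimated correlation). Mx1, an antiviral GTPase, changed by -1.25 (SE 0.52; limma adjusted p = 0.337) and Ifit3 by -1.33 (SE 0.36; limma adjusted p = 0.242). This list stood 0.37 above LPS 1 and LPS 2 in LPS 3 and had a median of -1.60 in cpdA 3. Glycolysis and hypoxia genes had a median of -0.24 (camera adjusted p = 0.00024; adjusted p = 0.628 with an estimated correlation), and cholesterol synthesis genes, the targets of SREBP2, a median of -0.36 (camera adjusted p = 0.0024; adjusted p = 0.770 with an estimated correlation). Cell cycle genes had a median of 0.41 (camera adjusted p = 0.0028; adjusted p = 0.763 with an estimated correlation), beside a median of -0.66 in LPS 3. LXR targets, which include genes of cholesterol export and of fatty acid synthesis, had a median of -0.32, NF-kB feedback genes -0.21 and chemokines -0.40 (camera adjusted p = 0.0155, 0.0155 and 0.0445). With an estimated correlation their adjusted p was 0.597, 0.770 and 0.770.

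Among other cell types, markers of monocyte-derived and dendritic cells had a median of -0.23 and those of mesothelium, fibroblast and endothelium -0.23 with DHA (camera adjusted p = 0.0118 and 0.0394). With an estimated correlation their adjusted p was 0.628 and 0.722. The mesothelium, fibroblast and endothelium list had a median of 0.61 in LPS 3 against LPS 1 and LPS 2. Its call held in 8 of 19 other settings and was lost without cpdA 3 and LPS 3 (median -0.06, camera adjusted p = 0.747). Macrophage markers had a median of 0.23 (camera adjusted p = 0.514). In all, camera called 13 of 32 lists for DHA, 5 up and 8 down. None kept its call with an estimated correlation (smallest adjusted p = 0.096), and the 9 other ways of splitting these 6 libraries into groups of 3 called 8 to 10 lists. The other 12 called lists, in the fit without cpdA 3 and LPS 3, kept their direction and camera call, but the median of the cell cycle list was 0.20, that of NRF2 targets 0.25, that of glycolysis and hypoxia genes -0.16 and that of cholesterol synthesis genes -0.71. That fit also called 6 further lists: SREBP1 targets, the fatty acid synthesis genes (median -0.50), heat shock genes (0.13), proinflammatory cytokines (-0.37), mast cell, basophil and eosinophil markers (-0.48), antimicrobial and oxidative effectors (-0.12) and inflammasome genes (-0.14). Their camera adjusted p was 3.2e-05, 0.00218, 0.00282, 0.00609, 0.0126 and 0.0296. LPS 3, the control left out, had medians of -0.50 for SREBP1 targets, 0.32 for heat shock genes, -0.84 for cytokines and -0.455 for effectors. Each lay beyond those of all 3 DHA libraries in the called direction, so these calls depend on leaving LPS 3 out. Mast cell, basophil and eosinophil markers (0.225) and inflammasome genes (0.10) went the other way in LPS 3. None of the 18 called lists of that fit kept the call with an estimated correlation (adjusted p from 0.284 to 0.756). By fry, which asks whether a list moves one way and not whether it differs from other genes, 6 of 32 lists were called there.

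The chemokine list was called lower for DHA, as above, but neither the proinflammatory cytokine list nor a single inflammatory gene named here passed its test with all 9 libraries. Of 19 other settings, the chemokine call held in 12. The cytokine list had a median of -0.10 and a mean of 0.01 (camera adjusted p = 0.531). In the fit without cpdA 3 and LPS 3 its median was -0.37, with 17 of 21 genes negative, 6 called lower and 1 higher (camera adjusted p = 0.00282; adjusted p = 0.744 with an estimated correlation). The list's median in LPS 3, the control left out, was -0.84 against LPS 1 and LPS 2, lower than in any DHA library. Tnf, the cytokine tumour necrosis factor, changed by -0.13, Il6 by -0.10, Il1b by 0.20 and Il12b, a subunit of interleukins 12 and 23, by 0.17 (limma adjusted p = 0.917, 0.982, 0.949 and 0.932). Ccl2, the main monocyte chemoattractant, had 36787 ± 2032 normalized counts in LPS and 16454 ± 1967 in DHA + LPS (SD, n = 3; limma adjusted p = 0.293). That p rests on a spread estimated over all 9 libraries, cpdA 3 included. Nos2, the inducible nitric oxide synthase, changed by -1.26 and Il1rn, the interleukin 1 receptor antagonist, by -1.30 (limma adjusted p = 0.588 and 0.214). Il10, an anti-inflammatory cytokine, changed by -1.90, Ptgs2, the inducible cyclooxygenase, by 0.15, Arg1, an arginase of alternatively activated macrophages, by 0.35, and Abca1, a cholesterol exporter, by -0.47 (limma adjusted p = 0.273, 0.950, 0.434 and 0.299). With LPS 3 left out, Tnf was at -0.41, Il6 at -0.66, Il1b at -0.27, Il12b at -0.12, Ptgs2 at -0.25 and Il10 at -1.26, none past the test.

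**Figure D2:**
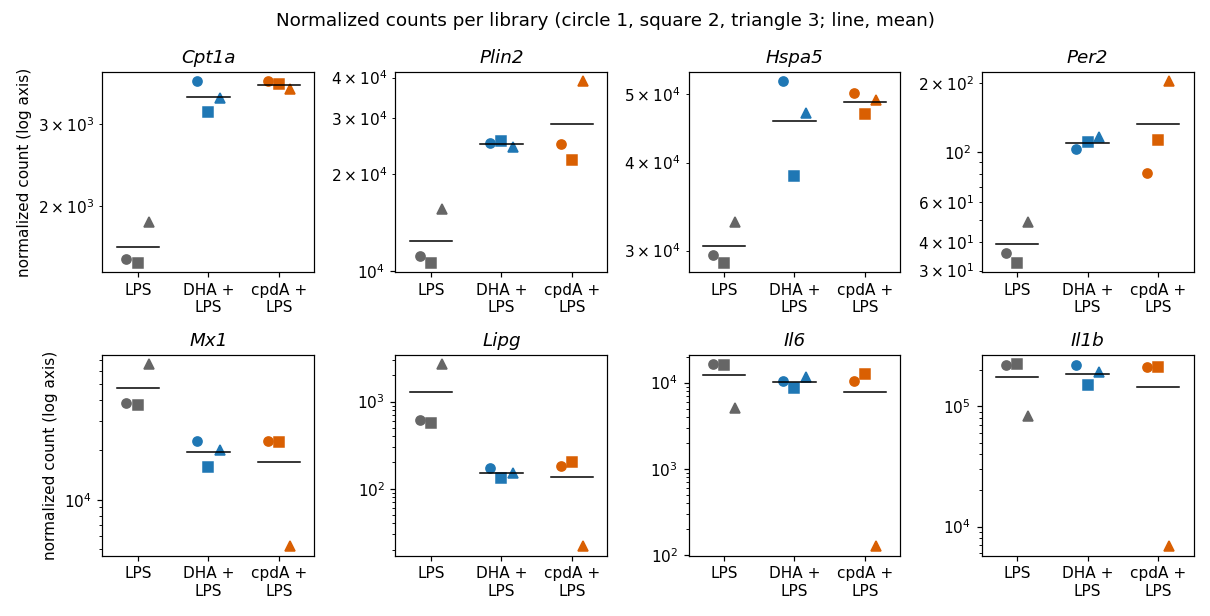
Normalized count (log axis) of 8 genes in each library by group; circles, squares and triangles are replicates 1, 2 and 3 and the line is the mean (n = 3). Cpt1a lay between 3436 ± 267 in DHA + LPS and 3647 ± 69.7 in cpdA + LPS against 1628 ± 191 in LPS (mean ± SD), while Il6 had 126 in cpdA 3.

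A fit without cpdA 3 and LPS 3, chosen after seeing the data, called 943 genes for DHA, 382 higher and 561 lower, by limma with Benjamini-Hochberg adjustment. By the fixed rule for named genes, applied to this fit, the largest rises were in Nat8l, which makes N-acetylaspartate (log2 change 3.21), Slc27a6, a fatty acid transport protein (2.03), Aatk (1.75) and Per2, a repressor of the circadian clock (1.66). Lrrn4, Peli2, N4bp3, Eef2k, Bbs9 and Cnnm2 followed, with changes from 1.63 to 1.49. The Lrrn4 value of 1.63 depends on leaving out LPS 3: with all 9 libraries it was 0.88 (limma adjusted p = 0.541), and without LPS 2 alone it was 0.38. Among the falls below, without 1 other LPS library alone, Lipg was at -3.08 and Timd4 at -0.85 (LPS 2), Il1rn at -1.50 (LPS 2) and Gm15056 at -2.45 (LPS 1). The largest falls were in Art2a-ps, a pseudogene (-2.43), Lipg, the endothelial lipase (-1.96), Mmp10, a matrix metalloproteinase (-1.94), and Ccl12, a monocyte chemoattractant (-1.63). Stra6, a retinol transporter (-1.44), Timd4, a receptor of resident peritoneal macrophages (-1.39), Spag1 (-1.35), LOC100862578 (-1.65), LOC664787 (-1.45) and Gm15056 (-1.47) also fell; reads of these last 3 and of Art2a-ps can be shared with near-identical copies, so their values are uncertain. In this fit Plin2, the coat protein of lipid droplets, rose by 1.20 (SE 0.09), Hilpda by 0.84 and Herpud1 by 1.14, while Ccl2 fell by 1.21 (SE 0.11), Nos2 fell by 1.05 and Il1rn fell by 0.90. Il6 fell by 0.66 (limma adjusted p = 0.0119) and Abca1 fell by 0.58 (limma adjusted p = 0.0462), whereas Tnf changed by -0.41 (limma adjusted p = 0.172) and Il1b by -0.27 (limma adjusted p = 0.324). Of 25 cholesterol synthesis genes, 21 fell (21 adjusted over the list alone), and of 40 interferon-stimulated genes, 26 fell (39 adjusted over the list alone). 15 of 22 ER chaperones rose (16 adjusted over the list alone), as did 11 of 31 PPAR targets (15 adjusted over the list alone). Their camera calls were lost with an estimated correlation (adjusted p = 0.321, 0.517, 0.440 and 0.284). In LPS 3, the control left out, the cholesterol synthesis median was -1.02, lower than in DHA 1, 2 and 3 (-0.78, -0.68 and -0.69). The fall of that list thus depends on leaving LPS 3 out. Interferon-stimulated genes, ER chaperones and PPAR targets had medians of 0.37, -0.0072 and -0.11 in LPS 3. Mast cell, basophil and eosinophil markers moved in the same fit, with a median of -0.48 and 2 of 8 lower (camera adjusted p = 0.00609; adjusted p = 0.517 with an estimated correlation), as did markers of monocyte-derived and dendritic cells, with a median of -0.33 (camera adjusted p = 0.00251; adjusted p = 0.517 with an estimated correlation). Of the genes called higher, 95.6% were also higher in cpdA 3 than in LPS 3, the pair left out, against 49.1% of all genes, and of those called lower, 98.4% were lower, against 50.8%. Another split of the 5 libraries, DHA 2 and DHA 3 against LPS 1, LPS 2 and DHA 1, called 1524 genes, more than the groups did. Leaving out DHA 1 as well gave 3210 genes for DHA, and leaving out cpdA 1 as well gave 618.

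The comparison of cpdA + LPS with LPS asks the same question of the Gpr120 agonist. Cpt1a rose again, from 1628 ± 191 to 3647 ± 69.7 normalized counts (SD, n = 3), a log2 change of 1.17 (SE 0.11; limma, Benjamini-Hochberg adjusted p = 0.0183), with all 3 cpdA libraries above all 3 LPS libraries. With the replicate number as a block the call was lost (limma adjusted p = 0.133, log2 change 1.17, SE 0.11). In a blocked fit of the 6 LPS and cpdA libraries alone, added after seeing the data, its adjusted p was 0.293. As lists, ER chaperones, NRF2 targets, PPAR targets and integrated stress response genes rose, and interferon-stimulated and cholesterol synthesis genes fell, each by camera with its preset correlation. None of these calls held with an estimated correlation (smallest adjusted p = 0.096, limma). Cpt1a was the 1 gene past the limma test, with 2030 genes at an unadjusted p under 0.05. The edgeR test called 1 gene and DESeq2 called 391. Left out singly, 6 libraries ended the Cpt1a call: its limma adjusted p was 0.238 without LPS 1, 0.212 without LPS 2, 0.0532 without DHA 1, 0.105 without DHA 3, 0.189 without cpdA 1 and 0.113 without cpdA 2. Without cpdA 3 limma called 3 genes and without DHA 2 it called 2.

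All 22 ER chaperone genes had a positive change with cpdA, with a median of 0.63. 0 passed over all genes and 16 were higher when adjusted over the list alone (camera adjusted p = 1.1e-17). The call was lost with an estimated correlation (adjusted p = 0.470), and fry gave an adjusted p of 0.0190. Manf, a secreted factor of the unfolded protein response, changed by 0.82 (SE 0.11; limma adjusted p = 0.0809). Herpud1 changed by 1.65, Hspa5 by 0.68 and Pdia4, a disulfide isomerase, by 0.96 (limma adjusted p = 0.132, 0.1995 and 0.178). The median in cpdA 3 was 0.84 against LPS 1 and LPS 2. Of 31 PPAR targets, 28 had a positive change with a median of 0.27, 1 passed over all genes and 7 were higher when adjusted over the list alone (camera adjusted p = 2.3e-09; adjusted p = 0.096 with an estimated correlation; fry adjusted p = 0.0104). Plin2 changed by 1.18 (SE 0.23; limma adjusted p = 0.161), Hilpda by 0.89 (limma adjusted p = 0.132) and Angptl4, a secreted inhibitor of lipoprotein lipase, by 0.94 (limma adjusted p = 0.178).

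Of 32 NRF2 targets, 30 had a positive change with cpdA with a median of 0.56, 0 passed over all genes and 7 were higher when adjusted over the list alone (camera adjusted p = 3.4e-10; adjusted p = 0.628 with an estimated correlation). Gclm, a subunit of the enzyme that starts glutathione synthesis, changed by 1.19 (SE 0.35; limma adjusted p = 0.230), Slc7a11 by 1.28 (limma adjusted p = 0.389) and Hmox1 by 0.82 (limma adjusted p = 0.252); with LPS 3 left out these values were 0.69, 0.43 and 0.497. Of 29 integrated stress response genes, 23 had a positive change with a median of 0.36, 0 passed over all genes, and 11 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 7.7e-06; adjusted p = 0.628 with an estimated correlation). Asns, the asparagine synthetase, changed by 0.51 and Trib3, a pseudokinase of this response, by 0.92 (limma adjusted p = 0.252 and 0.202). Atf3, a transcription factor of the list, changed by -0.13 (limma adjusted p = 0.725).

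All 40 interferon-stimulated genes had a negative change with cpdA, with a median of -0.86. 0 passed over all genes and 30 were lower when adjusted over the list alone (camera adjusted p = 4.9e-16; adjusted p = 0.628 with an estimated correlation). Mx1 changed by -1.72 (SE 0.52; limma adjusted p = 0.233) and Ifit3 by -1.42 (SE 0.36; limma adjusted p = 0.224). The median of this list was -1.60 in cpdA 3, and the Mx1 change was -1.02 without that library. All 25 cholesterol synthesis genes had a negative change, with a median of -0.58, and 1 was lower when adjusted over the list alone, with 0 over all genes (camera adjusted p = 4.3e-06; adjusted p = 0.700 with an estimated correlation). Sc5d and Acat2, enzymes of the sterol pathway, changed by -1.07 and -1.05 (limma adjusted p = 0.201 and 0.231). The median of this list was -1.02 in LPS 3 and -1.62 in cpdA 3.

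Chemokines had a median of -0.70 with cpdA, LXR targets -0.29, inflammasome genes -0.32, NF-kB feedback genes -0.27, proinflammatory cytokines -0.60 and SREBP1 targets, the fatty acid synthesis genes, -0.35. Their camera adjusted p was 0.0024, 0.00401, 0.00508, 0.0155, 0.0197 and 0.0233, and with an estimated correlation their adjusted p was 0.700, 0.470, 0.470, 0.770, 0.771 and 0.753. In cpdA 3 the chemokine median was -2.07 and that of the cytokines -2.72. Of 19 other settings, the cytokine call held in 12, and those of NF-kB feedback genes and SREBP1 targets in 13 each. The calls of the cytokines and the NF-kB feedback genes were lost without cpdA 3 and LPS 3, with medians of -0.07 and -0.03 (camera adjusted p = 0.510 and 0.567). Markers of monocyte-derived and dendritic cells had a median of -0.30 and those of mesothelium, fibroblast and endothelium -0.23 (camera adjusted p = 0.00197 and 0.0155; adjusted p = 0.628 and 0.647 with an estimated correlation). Camera called 14 of 32 lists for cpdA, 4 up and 10 down. None kept its call with an estimated correlation (smallest adjusted p = 0.096), and the 9 other splits of these 6 libraries called 9 to 14 lists. The mesothelium, fibroblast and endothelium list also lost its call without cpdA 3 and LPS 3 (median -0.08, camera adjusted p = 0.548). There the other 11 called lists kept their direction and camera call, with smaller medians for interferon-stimulated genes (-0.32), NRF2 targets (0.28), chemokines (-0.36) and LXR targets (-0.17). None of these 11 kept its call with an estimated correlation (adjusted p from 0.284 to 0.647), and fry called 5 of 32 lists in that fit. Heat shock genes (median 0.28), mast cell, basophil and eosinophil markers (-0.43, 8 of 8 negative), immediate early genes (0.18) and B cell markers (-0.17) were called in that fit and not with all 9 libraries. Their camera adjusted p was 9.1e-08, 0.00073, 0.0314 and 0.0332, and with an estimated correlation their adjusted p was 0.491, 0.517, 0.759 and 0.517. In the left-out cpdA 3 and LPS 3, heat shock medians were 0.03 and 0.32, and mast cell, basophil and eosinophil medians -0.11 and 0.225. Those of immediate early genes were -0.37 and -0.20, and of B cell markers 0.22 and -0.02. By these medians only the mast cell, basophil and eosinophil list kept its direction in that pair, and the others were reversed. With the replicate block the B cell call was lost (camera adjusted p = 0.0526).

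Inflammatory genes spread widely between cpdA libraries. Il6 changed by -2.10, Il1b by -1.25, Tnf by -0.41 and Il12b by -0.60 (limma adjusted p = 0.543, 0.650, 0.697 and 0.736). Ccl2 changed by -1.51, Nos2 by -2.44, Il1rn by -1.26 and Ptgs2 by -0.92 (limma adjusted p = 0.224, 0.322, 0.224 and 0.660). Il10 changed by -1.83, Arg1 by -0.08 and Abca1 by -0.46 (limma adjusted p = 0.252, 0.880 and 0.285). Without cpdA 3 the change of Il6 was 0.07, that of Il1b 0.40, that of Tnf 0.11, that of Il12b 0.42 and that of Ptgs2 0.31, while those of Nos2 and Ccl2 were -0.94 and -0.92. With LPS 3 left out as well, Il6 was at -0.49, Il1b at -0.06, Tnf at -0.17, Il12b at 0.12 and Ptgs2 at -0.08. None of these values passed the test. The Il10 change was -1.18 with LPS 3 left out, and the small Arg1 change lay between -0.22 and 0.0144 without 1 library at a time.

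**Figure D3:**
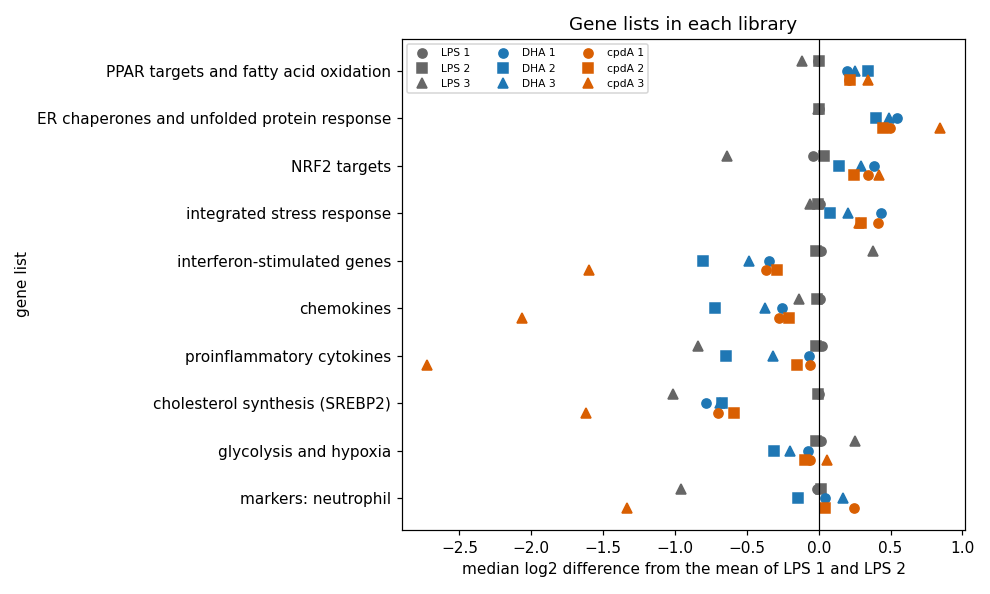
Median log2 difference of 10 gene lists in each library from the mean of LPS 1 and LPS 2; colours are groups and circles, squares and triangles replicates 1, 2 and 3. The proinflammatory cytokine median was -2.72 in cpdA 3 and -0.84 in LPS 3, and the ER chaperone median was 0.84 in cpdA 3.

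Without cpdA 3 and LPS 3, limma called 222 genes for cpdA, 99 higher and 123 lower, against 171 with the replicate block, 81 higher and 90 lower. Besides Cpt1a (log2 change 1.28), the largest rises were in Slc6a9, a glycine transporter (1.57), Il23a, a subunit of interleukin 23 (1.48), Per2 (1.45), Gpr155 (1.26), Efcc1 (1.24), Nr1d1, a repressor of the circadian clock (1.22), Rn7s1, the RNA of the signal recognition particle (1.15), Herpud1 (1.14) and Slc16a6, a monocarboxylate transporter (1.13). Il23a changed by -0.01 with all 9 libraries, and had 15.4 normalized counts in cpdA 3. With 1 of the 9 libraries left out at a time, Efcc1 lay between 1.29 and 2.25 and Nr1d1 between 0.73 and 1.06. The largest falls were in Lipg (-1.62), Mmp10 (-1.51), LOC100862578 (-1.43), Ccl12 (-1.26), Stra6 (-1.21), Acat2 (-1.15), Gm14446 (-1.14), Sc5d (-1.09), Treml2 (-1.08) and Serpina3h (-1.07). With all 9 libraries the changes of Lipg, LOC100862578, Ccl12 and Gm14446 were -3.37, -2.60, -2.34 and -2.68 (none past the test), and Treml2 lay between -1.78 without LPS 2 and -0.77 without LPS 3 alone. With the replicate block the 7-library calls of Efcc1, Rn7s1 and Mmp10 were lost (limma adjusted p = 0.0760, 0.0547 and 0.0567). Reads of Serpina3h, Gm14446, Rn7s1 and LOC100862578 may be shared with near-identical copies, so their values are uncertain. Plin2 rose by 1.11 (SE 0.10), while Ccl2 fell by 0.96 (SE 0.13), Nos2 fell by 0.73 and Il1rn fell by 0.73. Il6 changed by -0.49 (limma adjusted p = 0.136). Of 25 cholesterol synthesis genes, 17 fell (21 adjusted over the list alone), and 11 of 22 ER chaperones rose (16 adjusted over the list alone). In LPS 3, the control left out, the cholesterol synthesis median was -1.02, lower than in cpdA 1 and cpdA 2 (-0.70 and -0.59). 4 of 31 PPAR targets rose (9 adjusted over the list alone) and 2 of 40 interferon-stimulated genes fell (10 adjusted over the list alone), or 1 of 40 with the block. The camera calls of these lists were lost with an estimated correlation (adjusted p = 0.284, 0.357, 0.284 and 0.584). Beside them, mast cell, basophil and eosinophil markers had a median of -0.43, B cell markers -0.17 (call lost with the block, as above) and monocyte-derived and dendritic cell markers -0.21 (camera adjusted p = 0.00073, 0.0332 and 0.00242; adjusted p = 0.517 for each with an estimated correlation). Of the genes called higher, 92.9% were also higher in cpdA 3 than in LPS 3, and of those called lower, 97.6% were lower. Neither of the 2 other splits of the 4 libraries called a gene (0 of 13895 by limma). Leaving out cpdA 1 as well gave 8 genes for cpdA, and leaving out DHA 1 as well gave 730.

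The comparison of cpdA + LPS with DHA + LPS tests whether the effects of the pretreatments differed, at doses that differed too (10 µM and 100 µM). No gene passed. Cpt1a differed by 0.09 (SE 0.11), Plin2 by 0.16 (SE 0.23) and Hspa5 by 0.10. By limma 0 genes were called, with 142 at an unadjusted p under 0.05, and edgeR and DESeq2 also called 0. Without cpdA 3 and LPS 3 limma again called 0, with 700 at an unadjusted p under 0.05, and DESeq2 called 4. Leaving out DHA 1 as well, limma called 1215. That a test was not passed does not show that the compounds act alike.

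For gene lists, cell cycle genes had a median of -0.30 in cpdA + LPS against DHA + LPS, ER chaperones 0.12, glycolysis and hypoxia genes 0.12, alternative activation markers -0.20, cholesterol synthesis genes -0.22 and proinflammatory cytokines -0.58. Their camera adjusted p was 3.3e-07, 3.7e-05, 0.00014, 0.0076, 0.0097 and 0.0097, and with an estimated correlation their adjusted p was 0.628, 0.628, 0.628, 0.470, 0.771 and 0.770. Interferon-stimulated genes had a median of -0.21, neutrophil markers -0.50, NRF2 targets 0.11 and integrated stress response genes 0.06 (camera adjusted p = 0.0155, 0.0155, 0.0271 and 0.0341). With an estimated correlation their adjusted p was 0.808, 0.647, 0.770 and 0.770. Camera called 10 of 32 lists in all, and the 9 other splits of these 6 libraries called 8 to 13. Of these 10 calls, 6 were lost without cpdA 3 and LPS 3: cell cycle genes (median -0.04), ER chaperones (0.03), alternative activation markers (-0.11), cholesterol synthesis genes (0.04), neutrophil markers (0.12) and NRF2 targets (0.07), with camera adjusted p of 0.147, 0.678, 0.362, 0.302, 0.648 and 0.3797. Glycolysis and hypoxia genes (0.11) and integrated stress response genes (0.18) kept theirs (camera adjusted p = 0.0109 and 0.00286; adjusted p = 0.729 and 0.744 with an estimated correlation). The cytokine and interferon-stimulated lists went the other way, with medians of 0.21 and 0.22 (camera adjusted p = 2.0e-05 and 3.1e-09; adjusted p = 0.596 for each with an estimated correlation). That fit also called NF-kB feedback genes (median 0.22), chemokines (0.23), immediate early genes (0.16), antimicrobial and oxidative effectors (0.16) and heat shock genes (0.09), with camera adjusted p of 5.8e-06, 0.00026, 0.00207, 0.00251 and 0.0188. Their adjusted p was 0.635, 0.596, 0.647, 0.680 and 0.647 with an estimated correlation. Leaving out cpdA 3 alone gave 9 called lists, all 9 up.

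The changes with DHA and with cpdA were compared across the 13895 genes, which are not independent replicates. The log2 changes correlated with r = 0.79. Unchanged groups set against the same simulated LPS libraries gave 0.48 (central 95% of draws, 0.448 to 0.4996). The draws took genes as independent, while real libraries deviated from their group means together. LPS 3 and cpdA 3 did so at r = 0.437, and DHA 2 and cpdA 3 at 0.452. The simulated ranges are therefore too narrow, and values beyond them do not show agreement beyond such structure. The covariance was 0.134 against a simulated 0.0455, and 81.7% of genes had the same sign against a simulated 65.8%. Without cpdA 3 and LPS 3, r was 0.70 against a simulated 0.458, and the same direction was called in both comparisons for 89 higher genes, such as Cpt1a, Plin2 and Herpud1, and 121 lower genes, such as Ccl2 and Lipg. Over 100 draws of unchanged groups against the same simulated LPS libraries, 0 and 0.01 were shared on average (at most 0 and 1). Independent lists of these sizes would share 2.72 and 4.97. The first value leaves out the effects and the second the shared controls, so the excess over either is not a count of shared effects. No gene was called in opposite directions (0). With 3 LPS libraries the controls could not be divided into parts of at least 2, so part of the excess may come from the shared controls.

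Ffar4 (Entrez 107221), the gene of the receptor named in the series title, was near or below detection. It had 0 reads in 7 libraries, 2 reads in LPS 3 and 3 reads in cpdA 3. A count of 0 allows up to 6.69 normalized counts in DHA 1, the shallowest library, and up to 2.46 in cpdA 2, the deepest. These limits cover counting error only. Of the other genes of its list, 8 were kept, with a median of -0.01 for DHA and 0.05 for cpdA (camera adjusted p = 0.390 and 0.190).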

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

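Fits without cpdA 3 and LPS 3 together, alone or with a further library, with a batch term, with weights, without DHA 1 and cpdA 1, and blocked fits of cpdA against LPS on 6 or 7 libraries were chosen only after the results were seen; the other alternatives were planned. Values are given in the order DHA against LPS, cpdA against LPS and cpdA against DHA, by limma with Benjamini-Hochberg adjustment unless another tool is named. With all 9 libraries 1, 1 and 0 genes were called. A filter of 50 gave 3 genes for DHA, as did TMM scaling, and edgeR on whole reads gave 3 for DHA. DESeq2 on whole reads gave 315 and 391. Limma without trend and robust options gave 0 and 0, and the stricter threshold of 0.01 gave 0 and 0. Only the 6 libraries compared gave 9 and 0. Leaving out cpdA 3 and LPS 3 gave 943 and 222 by limma, 1157 and 290 by edgeR, and 1344, 388 and 4 by DESeq2. A batch term for these libraries gave 36 and 109, and library weights, 0.130 for cpdA 3, 0.223 for LPS 3 and 6.52 for DHA 3, gave 4303 and 563. Without DHA 1 and cpdA 1 there were 0 and 0. Without DHA 1, cpdA 3 and LPS 3 there were 3210, 730 and 1215, and without cpdA 1, cpdA 3 and LPS 3 there were 618 for DHA and 8 for cpdA. Other scalings and pseudocounts gave counts within 1.5 times of those with all 9 libraries. The cause of these shifts was not tested.

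Leaving out 1 library at a time gave 0 to 373 genes for DHA, 0 to 3 for cpdA and 0 to 0 for cpdA against DHA. The 373 and the 3 came without cpdA 3, which enters the DHA tests only through the shared estimate of spread. Cpt1a kept a positive change in each of these fits and under every scaling, from 1.02 to 1.18 for DHA and from 1.12 to 1.26 for cpdA. The replicate block, which joins libraries of the same number, called 0, 0 and 0 genes. 4 of 9 libraries correlated best with a library of their own number. Only for cpdA against LPS did the numbers meet the rule for pairing, which is no more than a hint. With the block the Cpt1a adjusted p was 0.144 for DHA and 0.133 for cpdA, with the changes as before, and camera called 13, 14 and 9 lists. For cpdA against LPS the block on those 6 libraries alone called 0 genes and 15 lists, and on 7 libraries 171 genes, Cpt1a among them (adjusted p = 0.00159), against 222 without the block, and 14 lists. The 15 lists included mast cell, basophil and eosinophil markers, lower with a camera adjusted p of 0.0379, against 0.166 with all 9 libraries and no block. The block changed no other call for cpdA with all 9 libraries, lists included.

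The correlation of the DHA and cpdA changes across genes ranged from 0.707 to 0.837 without 1 library at a time. It was 0.847 with a filter of 50, 0.697 with 7 libraries, 0.663 with library weights and 0.725 without DHA 1 and cpdA 1. With 1 called gene in either comparison, no correlation over called genes could be computed. Of gene lists, camera called 13, 14 and 10. With an estimated correlation it called 0, 0 and 0, with smallest adjusted p-values of 0.096, 0.096 and 0.470, and fry called 1, 2 and 0. With library weights camera called 5 for cpdA against DHA. Other alternatives gave list counts within 1.5 times of these, but the directions could shift. For DHA, camera called 5 lists up and 8 down with all 9 libraries, and 6 up and 4 down without LPS 1.

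Changes of these named genes had another sign than with all 9 libraries, where none of them passed the test. For cpdA, Il23a was 0.12 with a pseudocount of 8, 1.26 by edgeR and 1.26 by DESeq2 on whole reads, and 1.48 with 7 libraries (limma adjusted p = 0.00154, the 1 of these reversed values past the test), and from -1.02 to 1.98 without 1 library at a time. Atf3 was 0.0786 for DHA and 0.0690 for cpdA with quantile normalization, 0.0698 for cpdA with 7 libraries, and from -0.24 to 0.0129 for cpdA without 1 library at a time. Fth1 was 0 for DHA with quantile normalization. Aldoa for DHA was 0.00751 with TMM scaling, 0.00512 with median-of-ratios scaling, 0.177 with quantile normalization, 0.00859 by edgeR, 0.00683 by DESeq2 and 0.0259 with 7 libraries, and from -0.0585 to 0.0298 without 1 library. With quantile normalization Tnf was 0.0280 and Il6 0.0392 for DHA. With 7 libraries Il1b was -0.27, Il12b -0.12 and Ptgs2 -0.25 for DHA, and Il12b 0.12 for cpdA. Without 1 library at a time, the DHA change ranged from -0.41 to 0.0410 for Tnf, -0.66 to 0.19 for Il6, -0.27 to 0.44 for Il1b, -0.12 to 0.34 for Il12b and -0.25 to 0.36 for Ptgs2. The cpdA change ranged from -0.72 to 0.11 for Tnf, -3.25 to 0.0674 for Il6, -2.08 to 0.40 for Il1b, -1.16 to 0.42 for Il12b, -0.22 to 0.0144 for Arg1 and -1.59 to 0.31 for Ptgs2. For the cpdA changes of Tnf, Il6, Il1b, Il12b, Ptgs2 and Il23a the highest value came without cpdA 3, and the cause was not tested. At the depth of DHA 1, the shallowest library, 382 genes had a count of 0, so genes near the floor are least certain there.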

Other observations

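The clock gene list, its comparisons between replicates and all tests of unequal libraries and shared controls below were chosen only after the result was seen; the test on cpdA 3 minus LPS 3, the one-axis test and the splits were set before theirs. Several repressors and outputs of the circadian clock rose with both compounds in the fit without cpdA 3 and LPS 3. Per2 rose by 1.66 for DHA and 1.45 for cpdA (limma adjusted p = 0.000951 and 0.00664), and Cry1 by 0.89 and 1.02 (limma adjusted p = 0.00338 and 0.00614). Cry2 rose by 0.86 and 1.08 (limma adjusted p = 0.0081 and 0.00854), and Tef, a transcription factor of clock output, by 1.16 and 0.80 (limma adjusted p = 0.000926 and 0.0203). Per3, Nr1d2, Dbp and Gm129, also of the list of 11, did not pass for either compound. The activators Arntl, Clock and Npas2 changed by -0.05, 0.19 and 1.63 for DHA (limma adjusted p = 0.844, 0.263 and 0.063) and by 0.03, 0.20 and 0.42 for cpdA (limma adjusted p = 0.977, 0.499 and 0.846), so none passed, and the size of the Npas2 value leaves open whether the activators stayed unchanged. With all 9 libraries none of these passed; Per2 had an adjusted p of 0.194 for DHA and 0.161 for cpdA. A hypothesis is that pretreatment may shift the listed repressors and outputs of the clock as a set, whether or not other clock genes move with them. Its test does not decide: without Per2 and Nr1d1, which had drawn attention to it, the 9 remaining genes had a median of 1.37 in cpdA 3 minus LPS 3, at percentile 100 of 10000 random lists matched on expression, but that is 1 library against 1, and both stand apart. A difference between replicates alone also moved the list, to percentile 1.35 for cpdA 2 minus cpdA 3 (median -0.53, 0 of 9 positive). The other replicate differences lay at percentiles 6.41 to 91.8. Since cpdA 3 is part of the tested difference too, the shift there cannot be assigned to treatment. In the fit without cpdA 3 and LPS 3 the 9 genes had medians of 0.74 for DHA and 0.51 for cpdA, both at percentile 100. That fit had drawn attention to the clock, so it is no separate test. The time of day of harvest is not given in the labels, so time and treatment were not separated.

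Libraries cpdA 3 and LPS 3 stood apart from their replicates. Depth as the whole cause is argued against: at equal depth cpdA 3 stayed 12.3 times sampling noise from its nearest replicate, against 1.60 between LPS 1 and LPS 2. An exchange of their labels with each other is argued against too. Of the 222 genes called for cpdA without cpdA 3 and LPS 3, 95.5%, 212 genes, kept their direction in cpdA 3 minus LPS 3. That does not bear on an exchange with a DHA library, which was not tested. At equal depth cpdA 3 lay nearer to DHA 2 (7.13) than to its nearest replicate (12.3). A shared batch of cells or processing may be a cause. Deviations of cpdA 3 and LPS 3 from the group means correlated across genes with r = 0.437, but DHA 2 and cpdA 3 reached 0.452, so the test does not decide. Against LPS 1 and LPS 2, cpdA 3 was low in cytokines (-2.72), chemokines (-2.07) and interferon-stimulated genes (-1.60), whereas LPS 3 had -0.84, -0.14 and 0.37, so its LPS-induced lists did not move alike, and whether either library's cells responded less to LPS was not tested.

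DHA 1 was nearer to cpdA 1 than to its own replicates. Its low depth is argued against, since at equal depth the noise ratio was 1.26 to cpdA 1 and 3.24 to DHA 3. Libraries of the same number made together could give this, but DHA 2 lay 4.46 from cpdA 2 and 2.86 from DHA 3, which bears on number 2 alone. RNA of a cpdA culture in DHA 1 could too, with a ratio of 2.14 to cpdA 2, but DHA 3 was also nearer to cpdA 2 (2.496) than to DHA 2 (2.86). These explanations cannot be told apart with 3 libraries per group, and similar effects of the compounds stay open.

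Changes with DHA and cpdA went together. The shared LPS libraries as the whole cause are argued against by differences that share no library. The DHA change from LPS 1 and LPS 2 correlated across genes with cpdA 3 minus LPS 3 at r = 0.624. However, cpdA 3 and LPS 3 are single libraries that both stand apart. Their difference correlated less, at 0.468, with the change of cpdA 1 and cpdA 2 against LPS 1 and LPS 2. Its likeness to the DHA change therefore need not come from cpdA. The likeness of DHA 1 and cpdA 1 as the whole cause is argued against too, since r was 0.725 without them. That is above the central 95% of simulated draws, 0.353 to 0.414, but the draws took genes as independent and leave out variation that libraries share. One axis along which all libraries vary may contribute. DHA 2 minus DHA 3 correlated with the change of cpdA 1 and cpdA 2 at r = 0.109, between the bounds of 0.1 and 0.3 set for it. Such an axis thus cannot be told apart from shared effects, and its test did not use cpdA 3 or LPS 3. A shared effect of DHA and cpdA remains a hypothesis. Both treated groups had a pretreatment step, and the labels give none for the LPS group. An effect of that step common to both treated groups cannot be told apart from an effect of the compounds.

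With 6 libraries in groups of 3 there are 10 splits, too few for a share under 0.05. For genes called by limma, the groups gave 1 for DHA and 1 for cpdA, with 1 of 10 splits as high in each and 0 as the highest other count. For cpdA against DHA the groups gave 0, all 10 splits gave as many, and the highest other, DHA 1, cpdA 1 and cpdA 2 against DHA 2, DHA 3 and cpdA 3, gave 270, which points to a structure of the samples that the groups do not describe. For lists, the groups gave 13 for DHA (1 of 10 splits as high, highest other 10), 14 for cpdA (3 of 10, highest other 14) and 10 for cpdA against DHA (8 of 10, highest other 13). In the 7-library fit the split of DHA 2 and DHA 3 from LPS 1, LPS 2 and DHA 1 gave 1524 genes against 943, and DHA 1, cpdA 1 and cpdA 2 against DHA 2 and DHA 3 gave 1974 against 0. For lists the 7-library groups gave the highest counts for DHA (18, others 1 to 14) and for cpdA (15, the 2 others 1 each), but not for cpdA against DHA (9, others 1 to 14). List counts of cpdA against LPS with all 9 libraries, and of cpdA against DHA in either fit, therefore do not separate treatment from differences between libraries. For DHA in either fit, and for cpdA with 7 libraries, the groups gave the most lists, in 10 and 3 splits, too few for a test.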
